A study of Arabidopsis thaliana with 4 samples.

How the data were processed

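RNA was sequenced from the first leaf of 14-day-old Arabidopsis thaliana plants grown on Murashige and Skoog plates with 1% sucrose. There were 4 libraries in 2 groups of 2, the inbred accession Ak-1 and the hybrid named Col-0xAk-1, whose other parent Col-0 is the reference accession of the species. Groups and replicate numbers were taken from the sample titles. The names conflict: titles and strain say Ak-1, the genotype label says Aa-0, and the design text says Ak-0, so the inbred parent is called Ak-1 here as the titles have it. No label says that the replicates came from separate plants or pools, so the p-values measure only the spread between these libraries, which may be technical. The Col-0 parent was not analysed here, so no mid-parent value was computed.

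Per the labels' protocols, RNA was extracted with an RNeasy plant kit and libraries were made from total RNA with the Illumina TruSeq RNA kit V2, which does not mark strand. Sequencing was on an Illumina HiSeq instrument. Each deposited file gives 1 FPKM value per locus (fragments mapped to a transcript, scaled by its length and by the mapped fragments of the library, as the authors normalized them), rounded to 2 decimals, for 34133 loci. The submitters' processing notes name TopHat2 2.0.8b, TopHat, Cufflinks 2.0.2, edgeR 3.12.0 and the TAIR10 build. Which tool did which step, and how reads matching several loci were treated, is not given in the sources used here. FPKM values are not counts, so no count model was used.

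The total depth of each library is unknown. Steps between the lowest values gave relative depths of 1.13 for Ak-1 replicate 2, 1.35 for hybrid replicate 1 and 1.17 for hybrid replicate 2, against 1 for Ak-1 replicate 1. Values above 0 were listed for 21031 and 21261 loci in the Ak-1 libraries and for 21398 and 21752 in the hybrid libraries. An exact 0 may be a failed estimate, because RBCS1A, which leaf cells use at a high level, is listed at 0 in both hybrid libraries; such genes are given by their value in each library. The reference annotation used for names was of build TAIR10.1, so none of its coordinates are printed; 31416 of the 34133 loci matched it, and it was used for names, classes, neighbours and overlaps. Loci overlapped by another over at least 80% of the shorter one (1267 loci) are called overlapped loci; without strand their reads cannot be told apart from those of the partner.

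FPKM were used as deposited. The 15905 loci with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), hybrid minus Ak-1, two-sided, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; every adjusted p of a gene given in the text comes from limma unless another test is named. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values. With 2 residual degrees of freedom, the fit borrowed 3.18 prior degrees of freedom across genes. The lists, tests, named-gene rule and most alternatives were set before the data were examined.

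A total of 26 gene lists with 559 entries were fixed from textbook knowledge of leaf biology: salicylic acid defence, NLR and RPW8-type resistance genes, jasmonate, rapid stress and touch response, auxin, gibberellin and brassinosteroid synthesis, cell cycle, organ size, cell wall expansion, circadian clock, flowering time, photosystems, chlorophyll synthesis, starch, senescence, aliphatic glucosinolates, indole glucosinolates with glucosinolate breakdown, flavonoids, cold and abscisic acid response, heat shock proteins, markers of roots, shoot apex and flowers, stomata, vasculature and trichomes, and reference genes. The 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way. Both rest on the 2 residual degrees of freedom, so they can call few lists here. Counts adjusted over the list alone use the same limma p-values. Named genes were the 8 largest rises and 8 largest falls among called nuclear genes whose groups did not overlap, and from each list up to 3 called members with the largest change or, where none was called, the 1 with the smallest adjusted p. Any other gene is said to have been chosen after its values were seen. Loci under 0.1 FPKM in both libraries of one group and at least 1 FPKM in both of the other were counted without a test.

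The procedure was tested on simulated data for this comparison with 15905 loci. It recovered 46 of 67 genes changed by 1 on the log2 scale, 66 of 67 changed by 2 and 66 of 66 changed by 3, and it called 15 of 15685 unchanged genes. The simulated noise was independent between genes and of equal spread in both groups, and changed genes were drawn from those with higher values. In the data the hybrid pair differed more than the Ak-1 pair, so recovery may be lower and false calls more frequent there. Alternatives were other pseudocounts, filters, scalings, variance models, thresholds and list tests, a replicate block, and leaving out each library. The crossed block and the fit without overlapped loci were added after seeing the data. Descriptive counts, Fisher's exact tests and random draws used Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and numpy 2.4.6, and plots used Matplotlib 3.10.9. Splits of the libraries into other groups and tests for outlying libraries were not made, because a group of 2 is too small for them.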

Results

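First-leaf transcriptomes of the inbred accession Ak-1 and of its hybrid with Col-0 were compared in a study of biomass heterosis, the larger growth of some hybrids than of their parents. There were 2 libraries per group, each with FPKM values for 34133 loci. FPKM summed to 717147 and 728396 in Ak-1 and to 741307 and 714890 in the hybrid, and the median over tested loci was 9.47 and 9.24 against 8.51 and 8.93 FPKM. Across the 15905 tested genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.990 between the Ak-1 libraries and 0.968 between the hybrid libraries. Between groups it was 0.926 to 0.944, and no pair of libraries was alike enough to be a single library deposited again. No locus differed by over 4-fold between the Ak-1 libraries and 74 did between the hybrid libraries, against 258 to 366 between groups, on the same scale. The hybrid libraries may not be replicates of the same cross, as described under other observations, which limits every hybrid mean and SD.

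**Figure D1:**
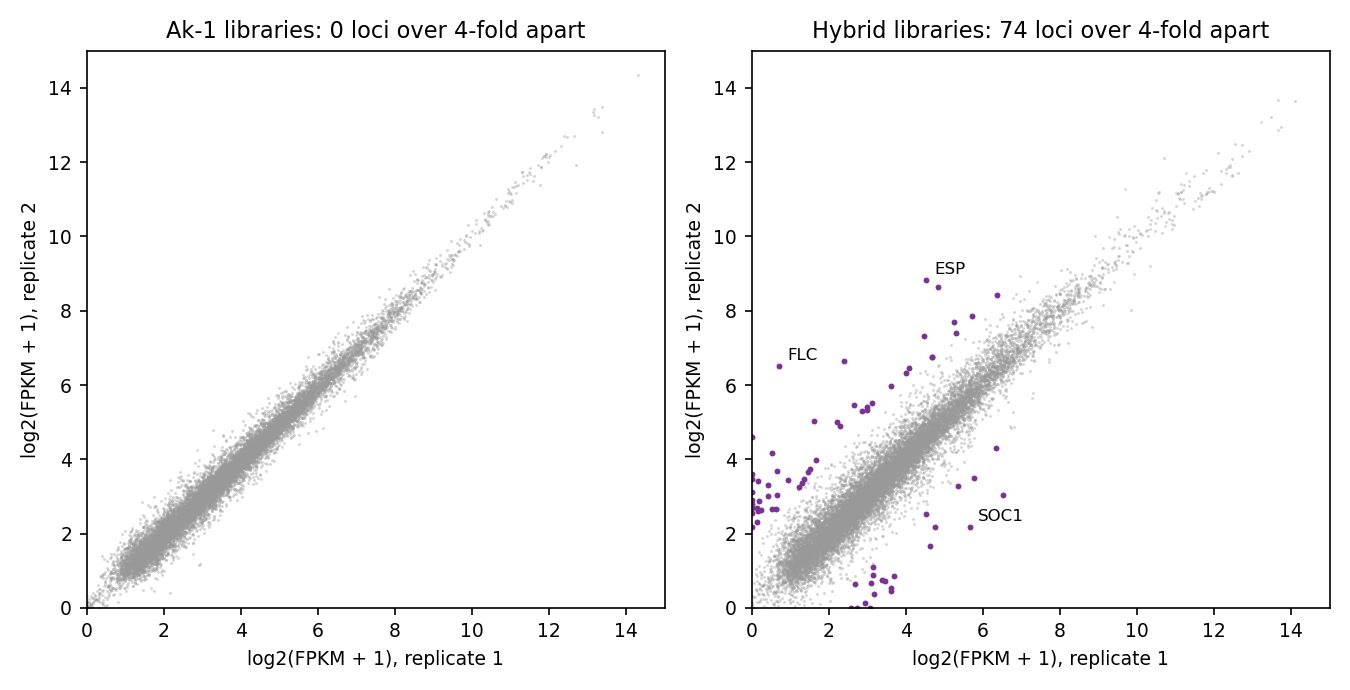
Each point is 1 tested gene, with log2(FPKM + 1) of replicate 1 on the horizontal and of replicate 2 on the vertical axis, for Ak-1 (left) and the hybrid (right). Purple points differ by over 4-fold, 0 in Ak-1 and 74 in the hybrid, among them FLC, ESP and SOC1, which were chosen after their values were seen.

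In hybrid leaves, 10 of 24 genes of cold and abscisic acid response, 6 of 20 of rapid stress response, 4 of 21 of jasmonate synthesis and response and 4 of 17 of senescence were lower than in Ak-1 leaves, and none of them was higher. ECS1, ESM1, 3 of 27 resistance genes and a pair of auxin-responsive SAUR genes were higher. ECS1, which encodes a cell wall protein, rose from 1.67 ± 0.02 to 575 ± 81 FPKM (mean ± SD, n = 2 per group), 345 times the Ak-1 mean (log2 difference 7.75, SE 0.16, limma adjusted p = 3.22e-04). ESM1, which steers glucosinolate breakdown toward isothiocyanates, rose from 17.0 ± 2.01 to 423 ± 71.7 FPKM (log2 difference 4.56, SE 0.18, adjusted p = 0.00210). As the Col-0 parent was not analysed, the rises of ECS1 and ESM1 cannot be told apart from a Col-0 allele with a higher level of its own. The transcription factor gene WRKY53, which acts in senescence and defence, fell from 31.0 ± 10.4 to 0.395 ± 0.219 FPKM (log2 difference −4.49, SE 0.27, adjusted p = 0.00447). The lipid transfer protein gene LTP4 fell from 51.6 ± 3.22 to 1.54 ± 0.997 FPKM, with a log2 difference of −4.43.

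Of the 15905 genes tested, 257 were higher and 400 lower in the hybrid, and 1211 and 2002 had an unadjusted p under 0.05. The latter balance depended on scaling, with 1488 higher and 1665 lower after median-of-ratios scaling and 1662 higher and 1513 lower after quantile normalization. Protein-coding genes made up 210 of the higher and 343 of the lower calls. The mean in the hybrid was under 0.5 times that in Ak-1 for 386 called genes and over 2 times for 235. The median log2 difference over all tested genes was −0.06. Without Ak-1 replicate 1 or without Ak-1 replicate 2, when the spread comes from the hybrid pair alone, only 3 genes were called higher (ECS1, AT1G66100 and AT1G25098) and 1 lower (RBCS1A). Without hybrid replicate 1 there were 619 higher and 899 lower, and without hybrid replicate 2 there were 206 and 496. With no filter on low values 19 of the 44 called genes that the text names by its rule lost their call.

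**Figure D2:**
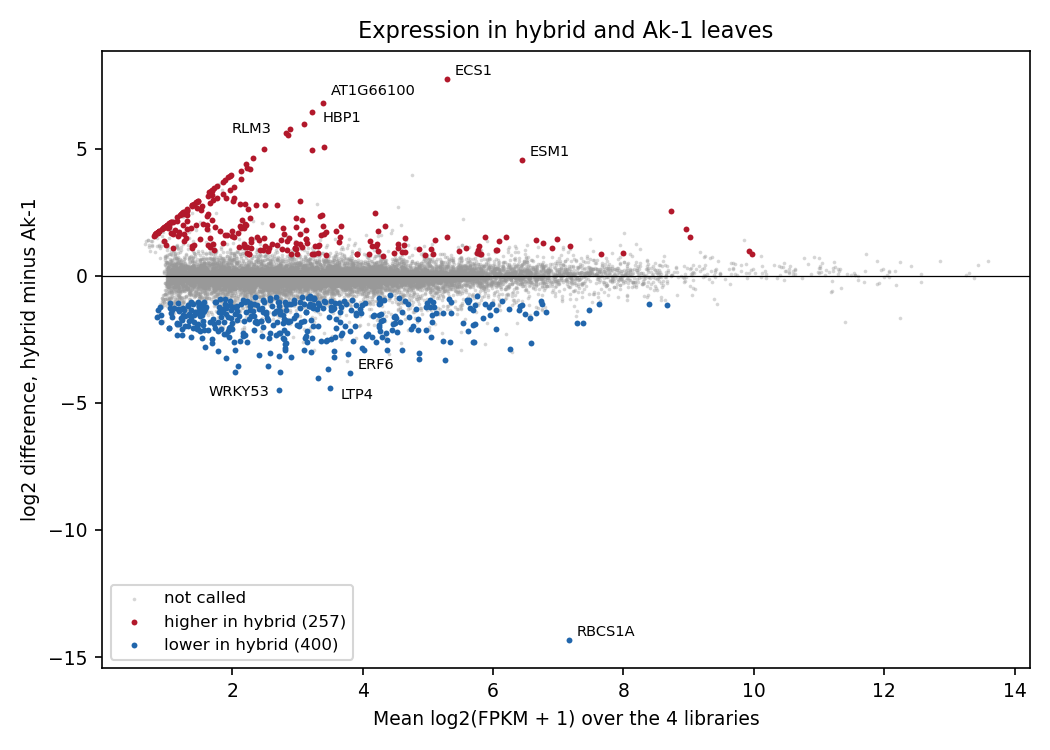
Each point is 1 tested gene, with the mean of log2(FPKM + 1) over the 4 libraries on the horizontal axis and the log2 difference, hybrid minus Ak-1, on the vertical axis. Called genes are red (257 higher) or blue (400 lower), and RBCS1A, at the bottom, is listed at 0 in both hybrid libraries.

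Among the 8 largest rises, 4 further genes with a known product were near 0 in Ak-1. Col-0 is the reference accession, so a gene missing or diverged in Ak-1 can be listed at or near 0 there without a change of expression. The thionin gene AT1G66100, a member of a family of small antimicrobial peptides, was listed at 0 in both Ak-1 libraries and at 96.6 and 123 FPKM in the hybrid. HBP1, for a heme-binding protein, was listed at 0 in both Ak-1 libraries and at 52.9 and 141 FPKM in the hybrid. RLM3, a TIR-domain gene for resistance to fungal pathogens, had 0 and 0.02 FPKM in Ak-1 and 38.0 and 62.5 in the hybrid. UBQ6, for a ubiquitin fused to a ribosomal protein, had 0.09 and 0.08 FPKM in Ak-1 and 56.2 and 79.4 in the hybrid. Its value is uncertain because ubiquitin genes have near-identical copies. AT4G34881 had 0.07 and 0.06 FPKM in Ak-1 and 36.1 and 64.7 in the hybrid. Another pair lie in overlapped loci, where reads cannot be assigned without strand. The non-coding locus AT1G25098 was listed at 0 in Ak-1 and at 54.8 and 51.4 FPKM in the hybrid, and AT1G72600 rose from 0.825 ± 0.035 to 60.9 ± 11.5 FPKM opposite GER1. The adjusted p from limma was at most 0.00646 (HBP1) for the 8.

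RBCS1A, a gene for the small subunit of the carbon-fixing enzyme Rubisco, had 20052 and 20897 FPKM in the Ak-1 libraries and was listed at 0 in both hybrid libraries (limma adjusted p = 1.23e-05). It was the only locus listed at 0 in both hybrid libraries and above 100 FPKM in both Ak-1 libraries. The 3 sister genes on chromosome 5 together had 19002 and 18880 FPKM in Ak-1 and 23055 and 20519 in the hybrid, while all 4 RBCS loci together had 39054 and 39777 FPKM in Ak-1. These genes are near-identical, so the division of reads among them is uncertain. A move of reads to the sisters alone is argued against, since all 4 together had only 23055 and 20519 FPKM in the hybrid. The 0 may be a failed estimate, which the limma test cannot tell from a fall. The other large falls, besides WRKY53 and LTP4, were in the ethylene response factor gene ERF6 (52.2 ± 12.3 to 2.91 ± 1.77 FPKM, log2 difference −3.82), in LOX4, a lipoxygenase gene of jasmonate synthesis (40.3 ± 16.2 to 2.21 ± 1.13 FPKM, −3.68), and in AT2G25735 (−4.04), AT1G69890 (−3.80) and AT5G09672 (−3.78), with adjusted p from limma of 0.00210 to 0.0214 for these 5.

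Near 0 in both Ak-1 libraries and at 1 FPKM or more in both hybrid libraries were 95 loci, of which 30 are overlapped loci, and 18 loci showed the reverse. The 95 included RLM3 and HBP1. As for the largest rises, genes missing or diverged in Ak-1 can be listed near 0 there. These counts cannot tell such genes from genes whose expression changed. RBCS1A was among the 18, and with at least 5 FPKM required in the expressed group it was the only locus left on that side, against 26 on the other. Without hybrid replicate 1 the 18 became 55 and without hybrid replicate 2 they became 34.

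Genes of rapid stress and touch responses were lower as a group. Of 20 tested members 6 fell, none rose and 14 were not called, and adjusted over the list alone 14 fell. WRKY33, a regulator of resistance to necrotrophic fungi, fell from 131 ± 41.1 to 21.5 ± 11 FPKM (log2 difference −2.61). Its call was lost with a mean of at least 5 FPKM required (limma adjusted p = 0.0504). ERF11, a repressor of ethylene responses, fell from 19.1 ± 5.69 to 1.26 ± 0.651 FPKM (−3.15). The list median was −1.86 (camera adjusted p = 1.48e-08, but adjusted p = 0.605 with an estimated correlation). The median against the Ak-1 mean was −2.38 in hybrid replicate 1 and −1.14 in hybrid replicate 2, and replicate 2 exceeded replicate 1 by 0.57 in Ak-1 and by 1.01 in the hybrid. The hybrid libraries had lower medians of this list and of those of jasmonate, cold and abscisic acid, senescence and heat shock (all 5 called with camera, each at adjusted p = 0.605 with an estimated correlation). They also had lower FPKM of the 18S ribosomal RNA locus AT3G41768, at 1670 and 4446 against 10547 and 7145 in Ak-1. Mitochondrial FPKM summed to 581 and 774 in the hybrid against 1177 and 1084 in Ak-1.

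Jasmonate genes also had falls and no rises, with 4 of 21 lower, 0 higher and 17 not called, and 11 lower adjusted over the list alone. JAZ10, a repressor of jasmonate signalling that jasmonate itself induces, fell to 0.71 and 3.03 FPKM in the hybrid libraries, with an Ak-1 mean 9.44 times the hybrid mean (log2 difference −2.83, SE 0.41, limma adjusted p = 0.0300, but 0.0568 with a pseudocount of 0.1), and the lipoxygenase gene LOX3 from 12.1 and 23.1 to 2.49 and 1.27 FPKM (−2.66; adjusted p = 0.0624 without hybrid replicate 2). The list median was −1.31 (camera adjusted p = 1.61e-04, adjusted p = 0.605 with an estimated correlation), at −1.52 in hybrid replicate 1 and −1.05 in replicate 2.

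Cold and abscisic acid response held the largest number of falls of any list, 10 of 24, with 0 rises and 14 members not called. Adjusted over the list alone 15 fell. RD26, a NAC transcription factor gene of abscisic acid and drought responses, fell from 240 ± 16.5 to 39.3 ± 18.9 FPKM (log2 difference −2.67), and LTP3, next to LTP4 in the genome and related to it in sequence, from 119 ± 3.84 to 11.2 ± 1.03 FPKM (−3.30). The median was −1.06 (camera adjusted p = 1.25e-08, adjusted p = 0.605 with an estimated correlation), at −1.18 and −1.10 in the hybrid libraries.

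Senescence and carbon starvation genes were lower for 4 of 17 members, higher for 0 and not called for 13, and 9 fell adjusted over the list alone. SAG14, a senescence marker, fell from 44.9 ± 11.5 to 7.05 ± 4.16 FPKM (log2 difference −2.59). Its call was lost with a mean of at least 5 FPKM required (limma adjusted p = 0.0504). The dark-inducible DIN1 fell from 319 ± 51.0 to 89.8 ± 39.2 FPKM (−1.88, limma adjusted p = 0.0499). That call was lost in several settings, such as median-of-ratios scaling with 0.0584 and a pseudocount of 0.1 with 0.0533. WRKY6 fell from 9.0 ± 0.813 to 3.89 ± 0.445 FPKM (−1.03). All 17 members had a negative log2 difference, with a median of −1.03 (camera adjusted p = 4.28e-06, adjusted p = 0.605 with an estimated correlation) that was −1.52 and −0.83 in the hybrid libraries. Heat shock proteins had a median of −0.64, with 1 of 9 members lower, 0 higher and 8 not called, and 1 lower adjusted over the list alone (camera adjusted p = 0.0281, adjusted p = 0.605 with an estimated correlation). The fall was in HSFA2, a heat stress transcription factor gene, from 3.89 ± 1.12 to 0.805 ± 0.346 FPKM (limma adjusted p = 0.0468), a call lost in several settings, such as median-of-ratios scaling with 0.0541, a pseudocount of 0.1 with 0.0552 and without hybrid replicate 2 with 0.0908. The call on the heat shock list was lost without Ak-1 replicate 1 (camera adjusted p = 0.188), hybrid replicate 1 (0.0662) or hybrid replicate 2 (0.10).

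**Figure D3:**
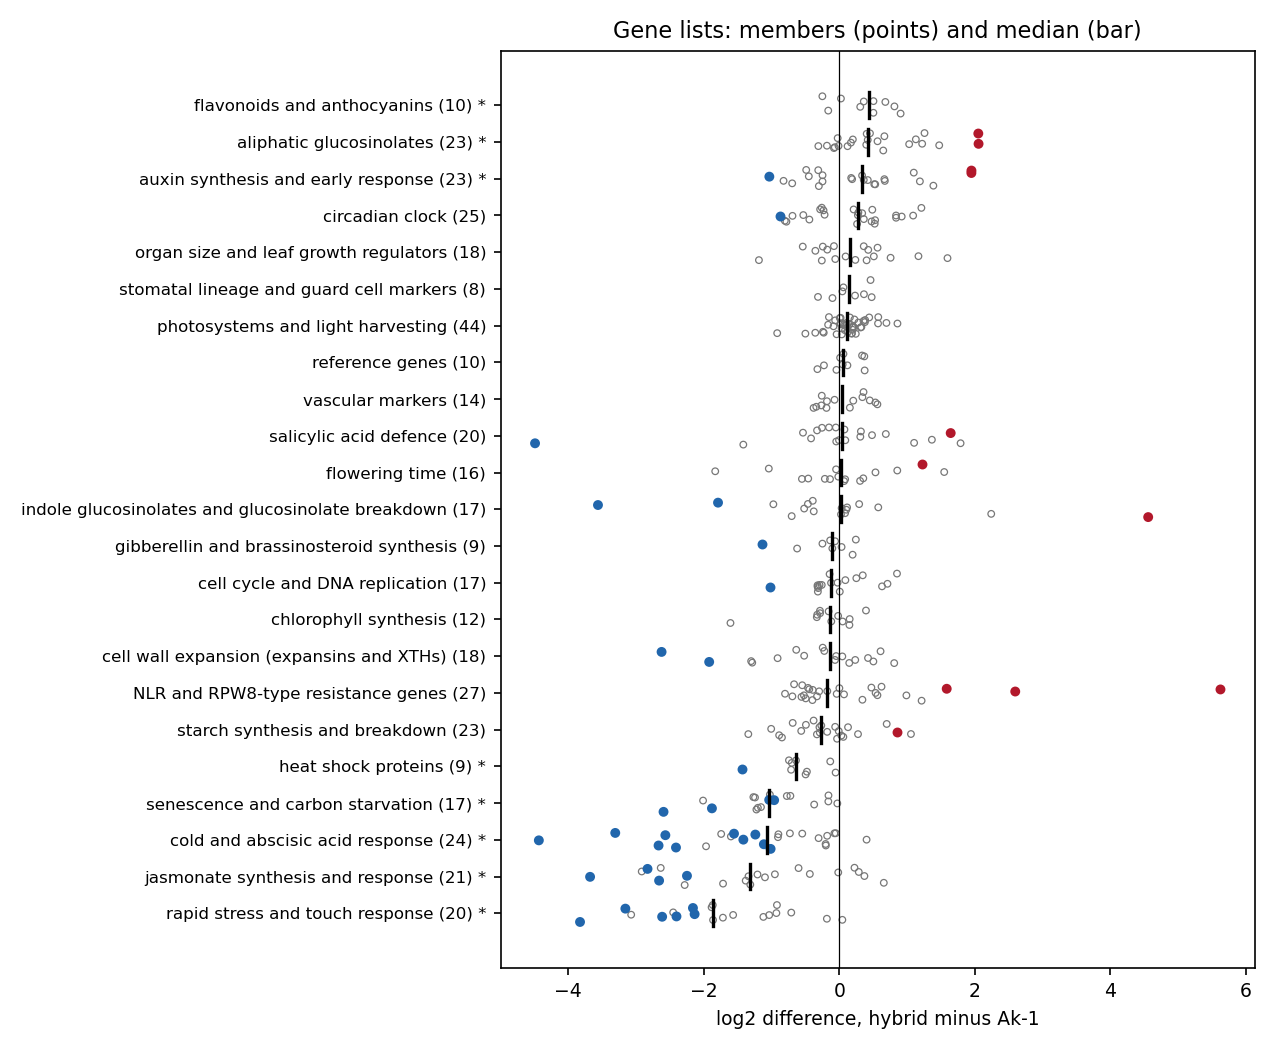
Points are the tested members of each list with at least 5 of them, placed by log2 difference, hybrid minus Ak-1 (horizontal axis), filled red or blue where called higher or lower, and bars are list medians; member numbers are in parentheses and an asterisk marks a camera adjusted p under 0.05. Medians of these lists run from −1.86 for rapid stress to 0.43 for flavonoids, and RBCS1A, listed at 0 in the hybrid, is left off the photosystem line.

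Aliphatic glucosinolate genes, which make methionine-derived defence compounds, were higher as a list, with 2 of 23 called higher, 0 lower and 21 not called, and the same 2 adjusted over the list alone. MYB29, an activator of the pathway, rose from 1.3 ± 0.636 to 8.56 ± 2.65 FPKM (log2 difference 2.05; adjusted p = 0.0580 without hybrid replicate 2), and FMOGS-OX2, for an enzyme of side-chain oxidation, from 0.440 ± 0.226 to 4.93 ± 0.085 FPKM (2.05). The list median was 0.42 (camera adjusted p = 1.61e-04, adjusted p = 0.605 with an estimated correlation). It was 0.04 in hybrid replicate 1 and 0.87 in hybrid replicate 2, and without replicate 2 the call was lost (camera adjusted p = 0.133). Flavonoid and anthocyanin genes had a median of 0.43 with 0 of 10 members called, 1 higher adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.605 with an estimated correlation). That median was 0.09 in hybrid replicate 1 and 0.71 in replicate 2, and without replicate 2 the adjusted p was 0.204. UGT75C1, for an anthocyanin glucosyltransferase, had 0.955 ± 0.233 FPKM in Ak-1 and 2.65 ± 0.198 in the hybrid (limma adjusted p = 0.0689).

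Indole glucosinolate and breakdown genes moved both ways, with 1 of 17 higher, 2 lower and 14 not called, and 1 higher and 3 lower adjusted over the list alone (median 0.03 but mean −0.04, camera downward, adjusted p = 0.591). Beside the rise of ESM1, CYP81F2, for an enzyme that modifies indole glucosinolates, fell from 19.2 ± 1.49 to 0.74 ± 0.453 FPKM (log2 difference −3.56). MYB51, an activator of their synthesis, fell from 15.1 ± 3.5 to 3.66 ± 0.997 FPKM (−1.79).

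Auxin synthesis and early response genes included 2 of 23 higher, 1 lower and 20 not called, and 4 higher and 1 lower adjusted over the list alone. SAUR20 rose from 5.48 ± 0.205 to 24.4 ± 5.90 FPKM and SAUR21 from 9.36 ± 0.205 to 39.1 ± 5.32 FPKM, each with a log2 difference of 1.95. These small auxin-induced genes promote cell expansion, and as similar neighbours they may share reads. GH3.5, for an enzyme that conjugates auxin to amino acids, fell from 8.32 ± 0.212 to 3.59 ± 0.750 FPKM (−1.03, limma adjusted p = 0.0404, but 0.0605 with a mean of at least 5 FPKM required and 0.0530 after rescaling nuclear loci to TPM). The list median was 0.34 (camera adjusted p = 0.0281, adjusted p = 0.605 with an estimated correlation). Without hybrid replicate 1 the adjusted p was 0.17, and it was 0.0682 with median-of-ratios scaling.

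Resistance genes of the NLR and RPW8 types had 3 of 27 members higher, 0 lower and 24 not called, and 7 higher and 3 lower adjusted over the list alone. They were RLM3, the RPW8 homologue HR4 (0.165 ± 0.064 to 6.09 ± 1.23 FPKM, log2 difference 2.60) and RPP7, for resistance to downy mildew (4.91 ± 0.368 to 16.8 ± 1.80 FPKM, 1.58), which has similar neighbours in its cluster. The median was −0.18 and the mean 0.29, opposite in sign (camera upward, adjusted p = 0.331). Of 20 salicylic acid defence genes, ACD6, which promotes defence at the cost of growth, rose from 4.99 ± 0.721 to 17.7 ± 1.49 FPKM (log2 difference 1.64), WRKY53 fell and 18 were not called, with 1 higher and 2 lower adjusted over the list alone (median 0.04, mean 0.01, camera adjusted p = 0.385, while fry pointed downward with adjusted p = 0.845).

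**Figure D4:**
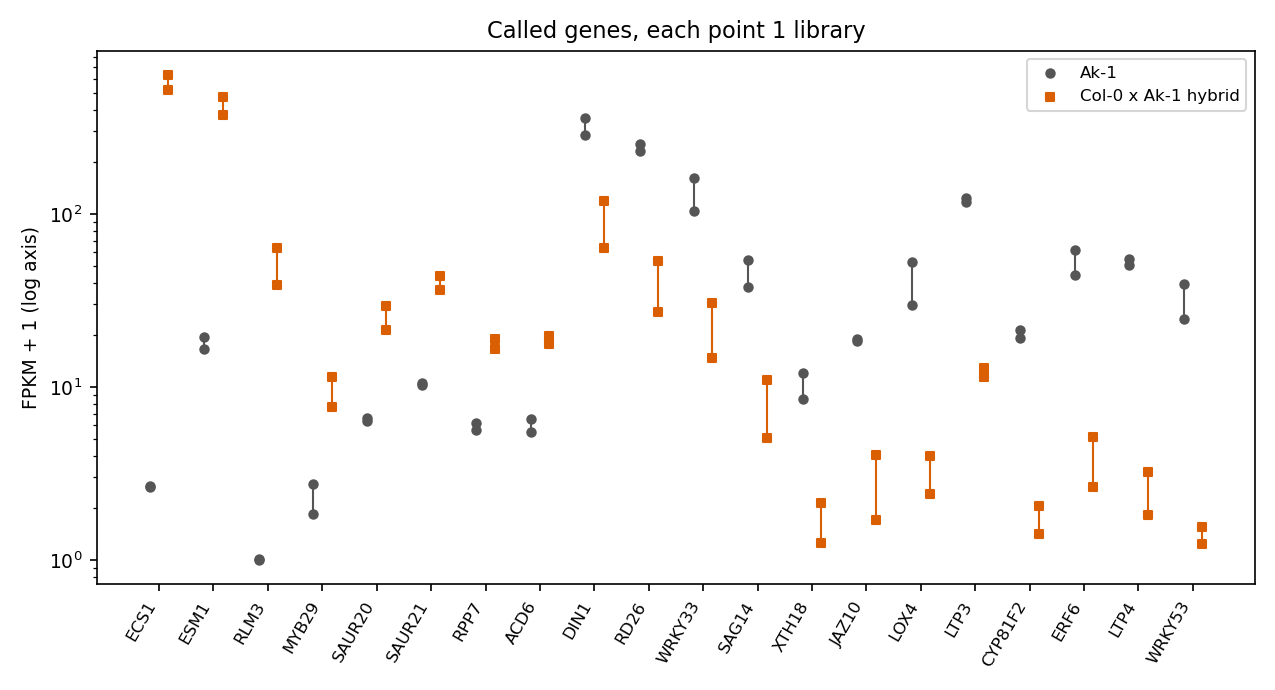
Each point is 1 library, with FPKM + 1 on a log vertical axis for 20 called genes (horizontal axis), grey circles for Ak-1 and orange squares for the hybrid, and a line joins the replicates of a group. ECS1, at 1.68 and 1.65 FPKM in Ak-1 and 517 and 632 in the hybrid, is farthest apart, and no gene shown has overlapping groups.

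In the cell cycle list 1 of 17 members was lower, 0 higher and 16 not called, the same adjusted over the list alone. It was CDC6, which licenses DNA replication and is an overlapped locus, and which fell from 2.68 ± 0.255 to 0.820 ± 0.127 FPKM (adjusted p = 0.0461, but 0.0714 without hybrid replicate 2 and 0.0600 with median-of-ratios scaling). The list median was −0.12, its mean −0.01 and camera pointed upward (adjusted p = 0.912). None of 18 organ size regulators was called by limma, with 4 higher and 1 lower adjusted over the list alone (median 0.17, camera adjusted p = 0.0843, but 0.0441 without Ak-1 replicate 2 and 0.0325 without hybrid replicate 2). Among them SMR1, an inhibitor of the cell cycle that promotes endoreduplication, had 54.0 ± 3.03 FPKM in Ak-1 and 91.9 ± 4.0 in the hybrid (limma adjusted p = 0.0552). Cell wall expansion genes had 2 of 18 lower, 0 higher and 16 not called, and 5 lower adjusted over the list alone (median −0.14, camera adjusted p = 0.331). The falls were in xyloglucan-modifying enzymes, XTH18 from 9.27 ± 2.43 to 0.705 ± 0.629 FPKM and XTH19 from 14.4 ± 0.806 to 3.08 ± 0.276 FPKM. Among 9 gibberellin and brassinosteroid synthesis genes, GA3OX1, which makes active gibberellin, fell from 21.1 ± 3.08 to 9.02 ± 0.318 FPKM (adjusted p = 0.0580 without hybrid replicate 2). The other 8 were not called, the same adjusted over the list alone (median −0.10, camera adjusted p = 0.441).

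Photosynthesis genes other than RBCS1A were not called: of 44 photosystem and light harvesting genes 1 was lower, 0 higher and 43 not called, the same adjusted over the list alone. The median was 0.12 and camera pointed upward (adjusted p = 0.0646), whereas the mean was −0.21 and fry pointed downward (adjusted p = 0.406). All of these include RBCS1A at 0, which weighs more on a mean than on a median. The median was 0.40 in hybrid replicate 1 and −0.15 in hybrid replicate 2. Camera's adjusted p was 1.62e-09 without replicate 2 and 0.00813 without Ak-1 replicate 2. None of 12 chlorophyll synthesis genes was called, also adjusted over the list alone (median −0.14, camera adjusted p = 0.654). PORB, for a light-dependent protochlorophyllide reductase, had 57.3 and 56.7 FPKM in Ak-1 and 33.2 and 9.62 in the hybrid (adjusted p = 0.193, and 0.00951 without hybrid replicate 1). For starch, APL3, a subunit of the first committed enzyme of its synthesis, rose from 4.93 ± 0.552 to 9.64 ± 0.184 FPKM (adjusted p = 0.0440, but 0.0541 without hybrid replicate 1, 0.0839 without hybrid replicate 2 and 0.0602 with a mean of at least 5 FPKM required). In all, 22 of 23 members were not called, the same adjusted over the list alone (median −0.27, camera adjusted p = 0.542).

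In the circadian clock list 1 of 25 members was lower, 0 higher and 24 not called, the same adjusted over the list alone (median 0.27, camera adjusted p = 0.0954, but 0.00768 with a mean of at least 5 FPKM required). It was RVE7, a clock-related MYB gene, which fell from 24.7 ± 1.88 to 13.0 ± 1.27 FPKM (adjusted p = 0.0438, but 0.0542 without hybrid replicate 1, 0.0514 without hybrid replicate 2 and 0.0555 with median-of-ratios scaling). In the flowering time list 1 of 16 was higher, 0 lower and 15 not called, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.307). SPL3, a promoter of flowering that is an overlapped locus, rose from 0.305 ± 0.191 to 2.02 ± 0.092 FPKM (limma adjusted p = 0.0415, but 0.0669 with a pseudocount of 0.1 and 0.0510 after rescaling nuclear loci to TPM). Its opposite-strand partner AT2G33815, chosen after its values were seen, fell from 1.87 and 2.12 to 0.38 and 0.44 FPKM. The length-weighted sum of the pair changed by a log2 of 0.10, so a rise of SPL3 cannot be told apart from a different division of their reads.

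Few markers of roots, of shoot apex and flowers or of trichomes passed the filter on low values, whereas most vascular and stomatal markers did. Of the root list only PYK10, a root glucosidase gene, was tested, with 0.31 and 0.82 FPKM in Ak-1 and 0.35 and 8.92 in the hybrid (limma adjusted p = 0.521, and 0.0187 without hybrid replicate 1). Of the shoot apex and flower list only the floral gene SEP3 was tested, with 2.09 ± 0.346 FPKM in Ak-1 and 0.690 ± 0.113 in the hybrid (adjusted p = 0.0838). Over the list alone it counted as lower, but with 1 member that is its unadjusted limma p of 0.00528. Among 3 trichome genes TRY had 7.82 ± 2.59 and 15.9 ± 3.69 FPKM (adjusted p = 0.141) and 0 were called, with 1 higher and 1 lower adjusted over the list alone. Lists this small were not tested with camera. None of 8 stomatal genes was called, also adjusted over the list alone (median 0.15, camera adjusted p = 0.162), and MYB60, a guard cell gene, had 9.73 ± 0.764 FPKM in Ak-1 and 13.8 ± 1.81 in the hybrid. The same held for 14 vascular genes (median 0.04, camera adjusted p = 0.307), where SWEET11, a phloem sucrose exporter gene, had 140.4 ± 4.82 and 204 ± 20 FPKM. None of the 10 reference genes was called, also adjusted over the list alone (median 0.06, camera adjusted p = 0.357), and MON1 had 20.4 ± 1.27 and 16.1 ± 0.297 FPKM.

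Of the 23 lists tested 3 were higher and 5 lower with camera. None was called with an estimated correlation (smallest adjusted p = 0.605) or with fry, which tests whether genes move on balance one way (smallest adjusted p = 0.113, for cold and abscisic acid response). Both rest on the 2 residual degrees of freedom and can call few lists, so they do not decide whether these lists moved. Among the lists called with camera the estimated correlation ran from −0.024 (auxin) to 0.90 (rapid stress). For cold and abscisic acid response it was 0.024, and the unadjusted p of camera with that correlation was 0.031. Among organelle transcripts, 13 of 36 tested mitochondrial loci were lower in the hybrid and 0 higher, with a median log2 difference of −0.91, and 2 of 74 chloroplast loci were higher and 4 lower, with a median of −0.07.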

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

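Most alternatives left both counts of called genes within 1.5 times the reported 257 higher and 400 lower, and no reported call changed sign under any of them; the crossed block and the fit without overlapped loci were chosen after seeing the data. With no filter on low values 178 genes were higher and 173 lower among 24073 tested. Requiring a mean of at least 5 FPKM gave 92 higher and 206 lower among 10836 tested and 5 lists higher, and an adjusted p under 0.1 gave 452 and 738. Leaving out 1 library at a time gave 3 to 619 higher and 1 to 899 lower, 3 to 530 called genes over 2 times and 1 to 815 under 0.5 times the Ak-1 mean, 2 to 5 lists higher, and 21 to 55 loci near 0 in the hybrid. In these fits the lone library of a group is assumed to vary like the other group, and without an Ak-1 library that is the hybrid pair, which differs more than the Ak-1 pair (r = 0.968 against 0.990). Only 4 of the 657 calls were also called without either Ak-1 library, against 588 without hybrid replicate 1 and 464 without hybrid replicate 2. With an estimated correlation 0 lists were higher and 0 lower, and fry gave 0 and 0. Loci near 0 in Ak-1 numbered 164 when near 0 meant under 0.5 FPKM and 26 when at least 5 FPKM was required in the hybrid, against 95 as reported. Loci near 0 in the hybrid numbered 103 and 1 under the same settings and 8 when listed at exactly 0, against 18. Apart from fewer genes or libraries in a fit, the cause was not tested. Other scalings gave 39.1% (as reported), 43.8% (median of ratios) and 46.8% (quantile) of calls higher.

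The labels share only a replicate number, which says nothing of a shared plate or day, and deviations of same-numbered libraries had a correlation of −0.138 across genes. With the replicate block 200 genes were higher and 365 lower, 482 of the 657 reported calls among them; GH3.5, CDC6, RVE7, SPL3 and APL3 lost their call and no list did. With the crossed pairing 262 genes were higher and 439 lower. Without overlapped loci 187 were higher and 317 lower. Of the 44 named genes called, 25 kept the call with no filter and 31 of 37 at 5 FPKM; the other scalings, pseudocounts and variance models kept 38 to 44. The unknown depth limits what an FPKM near 0 can show.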

Other observations

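All tests in this part were chosen after the results were seen, and so were the gene classes and the genes named for the first time here. Classes were taken from the names in the annotation and counted among 15208 tested nuclear loci without overlapped ones, of which 207 were higher and 327 lower in the hybrid; 14 classes in both directions gave 28 Fisher's exact tests, adjusted together. SAUR genes, small auxin-induced genes linked to cell expansion, stood out upward: 11 of 33 were higher (adjusted p = 9.49e-12) and 0 lower, 25 had a positive log2 difference, and the median was 1.00. Besides SAUR20 and SAUR21 these included AT1G29460, from 4.43 ± 1.36 to 19.9 ± 3.14 FPKM (mean ± SD, n = 2), AT4G38840, from 20.3 ± 1.61 to 54.8 ± 4.75 FPKM, and SAUR28, from 1.33 ± 0.354 to 5.88 ± 0.990 FPKM. Many SAUR genes lie side by side as similar copies, so their values are not independent. NBS-LRR resistance genes had 12 of 80 higher (adjusted p = 1.10e-08) and 1 lower around a median of −0.02; AT1G63360 was listed at 0 in both Ak-1 libraries and at 8.75 and 16.4 FPKM in the hybrid, and AT5G46490 had 0.17 and 0.26 FPKM against 9.28 and 17.2. Of the 78 such loci at 1 FPKM or more in both hybrid libraries 4 were near 0 in Ak-1, some of them among these 12. Resistance genes missing or diverged in Ak-1 would give such rises beside a Col-0 allele, so the test does not show that their expression changed. Of the 95 loci near 0 in Ak-1, 7 lie from AT1G24793 to AT1G25211, a stretch with copies of LpxC genes of lipid A synthesis.

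Transcription factor classes tied to stress and ageing leaned downward. NAC genes were lower for 8 of 43 (adjusted p = 2.95e-05), among them NAC019, an abscisic acid and jasmonate responsive gene, from 56.9 ± 13.7 to 6.54 ± 1.56 FPKM, and NAC102, from 102 ± 11.6 to 31.6 ± 2.93 FPKM. ERF genes were lower for 6 of 41 (adjusted p = 0.00126), with ERF4 from 107 and 149 to 20.8 and 19.3 FPKM, and WRKY genes for 5 of 29 (adjusted p = 0.00162), with WRKY28 from 4.99 ± 0.148 to 0.680 ± 0.127 FPKM. The NAC gene RD26, ERF6, ERF11, WRKY6, WRKY33 and WRKY53 are among the class members and were already given as falls from the fixed lists. The NAC, ERF and WRKY tests are therefore not independent of those lists. VQ motif genes, whose products bind WRKY proteins, were lower for 4 of 12 (adjusted p = 6.34e-04). Cytochrome P450 genes went both ways, with 7 of 92 lower (adjusted p = 0.0147) and 4 higher (adjusted p = 0.115) around a median of −0.03. Glutathione S-transferase genes did not pass (3 of 31 lower, adjusted p = 0.0994), nor did MYB, bHLH, F-box, UDP-glycosyltransferase and ribosomal protein genes in either direction. Genes with the word kinase in their annotated name, which are not all protein kinases, did not pass in either direction. MYB96, an abscisic acid responsive regulator of wax synthesis, fell from 45.1 ± 9.71 to 9.43 ± 0.530 FPKM.

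The hybrid libraries differed from each other in whole genes: 30 loci were under 0.1 FPKM in replicate 1 and at least 1 FPKM in replicate 2, and 21 the reverse, against 2 and 2 between the Ak-1 libraries. Of the 30, 19 were near 0 in both Ak-1 libraries too, so only hybrid replicate 2 expressed them. An example is AT4G19240, at 23.4 FPKM in hybrid replicate 2 and listed at 0 in every other library. The floral repressor gene FLC had 0.64 FPKM in hybrid replicate 1 and 89.6 in replicate 2 (2.52 and 3.94 in Ak-1), its target SOC1 49.6 and 3.49 (49.2 and 56.2), the glucosinolate breakdown gene ESP 21.9 and 449 (19.4 and 21.6), and AOP2, which Col-0 is known to lack in working form, 3.95 and 28.6 (2.66 and 4.18). Sampling noise is argued against, since 7 pairs of these loci lay within 5 loci of each other against a mean of 0.369 in 10000 random draws (permutation p = 0.0001, the smallest the draws can give). A candidate explanation is that replicate 2 holds no Ak-1 allele at some loci, as from another cross or a wrong label: of the 21 loci near 0 in replicate 2 alone, 16 were at 1 FPKM or more in both Ak-1 libraries, with replicate 1 at a median of 0.552 of the Ak-1 mean (0.371 to 0.972), against 2 of 30 near 0 in replicate 1 alone (Fisher's exact p = 3.24e-07). Growth or harvest conditions that differed between the hybrid libraries cannot be told apart from this by the rapid stress list, which was 1.01 higher in replicate 2 on the log2 scale, because no label gives conditions per library. Some clock genes differed too, such as LHY with 72.1 and 194 FPKM (57.2 and 53.1 in Ak-1) and GI with 4.84 and 1.78 (6.08 and 5.98). The clock list as a whole was higher in replicate 2 by a median log2 of 0.19.

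Nested genes on opposite strands often moved apart. Of 126 pairs that overlapped over at least 80% of the shorter locus, each locus at a mean of 1 FPKM or more, 26 moved over 2-fold in opposite directions and 1 in the same direction; 10000 shuffles of the partners gave a mean of 11.7 and at most 22 opposite pairs (permutation p = 0.0001, the smallest they can give), and loci that the annotation classes as lncRNA were called in 57 of 107 cases (53.3%) against 553 of 15477 protein-coding genes (3.57%). The nuclear gene YCF37, for a chloroplast protein, went from 1.04 and 0.38 to 54.0 and 47.2 FPKM while its partner AT2G23672 went from 105 and 102 to 42.1 and 39.2, and HYR1 from 40.7 and 38.4 to 7.62 and 8.5 while AT3G21755 went from 0 and 0.10 to 15.3 and 19.3. The reads of a pair may have been divided between its loci differently in the groups: opposite moves partly cancel in any sum, but the sum changed by a median absolute log2 of 0.430 in these pairs against a median of 1.08 in shuffled pairs chosen in the same way, which were not matched for level (permutation p = 0.0074). The lesser part of each length-weighted sum was a larger share in both hybrid libraries than in Ak-1 for 20 of the 26 pairs. For 3 pairs it was a smaller share. This one-sided difference between the groups cannot be told apart from genotype. A change of both transcripts stays open, since 7 of the 26 sums moved over 2-fold and the kit does not mark strand.

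The stress, jasmonate, abscisic acid and senescence lists were called lower with camera at the preset correlation, but not with an estimated correlation or fry. The latter tests rest on 2 residual degrees of freedom and can call few lists. Several explanations of the lower values are open. Reads shared with a locus that overlaps over at least 80% of the shorter one are argued against, as 1 of the 82 tested members (1.22%) is such a locus. Smaller overlaps were not counted and stay open, as only 660 of 3763 overlapping pairs reach 80%. Time of day at harvest stays open: the clock list moved from the Ak-1 mean by a median absolute log2 of 0.383 in hybrid replicate 1 and 0.657 in replicate 2, whereas the rapid stress list fell further in replicate 1, and 2 libraries cannot settle an order. Handling at harvest cannot be told apart from the groups either, as the rapid stress list differed by 0.568 between the Ak-1 libraries, which share a genotype, and no label gives handling per library; 18S FPKM, lower in both hybrid libraries, ran with the rapid stress list between the hybrid libraries (1670 and 4446) and against it between the Ak-1 libraries (10547 and 7145). The hybrid genotype itself may also lower these genes, which was not tested without the Col-0 parent.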
